A study of Mus musculus with 6 samples.

How the data were processed

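The series profiled WT1 and MAFB on chromatin of mouse podocytes, with 2 libraries for each factor and 2 input libraries, lettered A and B. Per the labels' protocols, kidneys of mice perfused with magnetic beads were digested, the glomeruli were collected with a magnet, crosslinked with formaldehyde and sonicated, and libraries were made with the MicroPlex kit. Glomeruli also hold endothelial and mesangial cells, and a step that purifies podocytes from them is not given in the sources used here. The labels name the antibodies as anti-WT1 (Santa Cruz) and anti-MAFB (Sigma). Whether A and B came from separate animals is not given. Genotype and age are also not given in the sources used here.

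Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, Trimmomatic, Trim Galore 0.6.7, Bowtie2 2.5.1, MACS2 and deepTools, with the builds mm10 and GRCm38, which are the same assembly. The notes give no order, roles or parameters. Per the file headers, each deposited list holds peak coordinates, an IDR score, the assigned gene and transcript, a genomic class and the distance to the transcript start. The score is a whole number that the authors deposited for each peak of the combined list, so peaks cannot be compared between replicate libraries. How the combined list was made, any exclusion of repeat regions and the gene annotation program are not given in the sources used here. Peak starts were counted from 0: adding 1 gave the deposited distance to the transcript start in 100.0% of peaks, and coordinates are printed counted from 1.

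These choices affect the measurements in several ways. A combined list keeps no spread between libraries. The WT1 score stops at 1000, so 5973 peaks tie at the top, and in both lists many peaks share a lowest score that is set apart from the next one (182 and 297 for WT1, 114 and 355 for MAFB). Under the usual scaling of the IDR program an IDR of 0.05 corresponds to a score of 540, which 9440 WT1 peaks (55.2%) and 237 MAFB peaks (49.8%) reach; the lists do not state the scaling. This score served as a stricter limit for both lists in an alternative. Assigning each peak to a gene by distance favours long genes and genes with wide intergenic flanks. Gene names of the lists were matched to symbols and unique synonyms of the RefSeq table for GRCm38.p6, which found 8495 of 9447 WT1 gene names (89.9%) and 366 of 415 MAFB gene names (88.2%). In the WT1 list 10 gene names had been turned into dates by a spreadsheet, and their 30 peaks were left out of the gene tests.

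Peaks overlapped when they shared at least 1 bp. The overlap was tested against 100000 random placements of the MAFB peaks within their chromosomes, one-sided. A second kind of placement put each MAFB peak at its own distance from the start of another transcript in the lists, and a further kind, chosen after the data were examined, moved it within 100 kb. Counts were compared with two-sided Fisher's exact tests, and medians with a two-sided permutation test of 100000 resamples. The 12 gene lists (246 different genes) were fixed before the data were examined, as were the main tests. They cover the slit diaphragm, the podocyte cytoskeleton, podocyte transcription factors, the basement membrane and adhesion, other podocyte genes, nephrotic syndrome, the Hippo pathway, glomerular endothelium, mesangium, tubule, macrophage and nephron progenitor. Each list was tested among 21896 protein-coding genes, with Benjamini-Hochberg adjustment over the 12 lists and a threshold of 0.05, and again with an exact test within 10 gene-length groups. The tests of genes with at least 5 WT1 peaks, of list genes outside the podocyte lists, of promoter against other MAFB peaks and of MAFB peaks at podocyte genes against others were chosen after the data were examined.

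Named genes followed a rule fixed before the data were examined. It takes up to 10 members each of the slit diaphragm, transcription factor and basement membrane lists in order of the peak score, the 10 genes with the highest-scoring peaks of each factor, up to 15 genes with shared peaks in order of the MAFB score, and Wt1, Mafb, Nphs1, Nphs2 and Podxl. Ties at the WT1 score limit were broken by peak length, a choice made after the data were examined. Genes named outside the rule, such as list members without a peak, Synpo, Actn4 and the MAFB-bound list members, were chosen after their values were seen.

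The list test was tested on 200 simulated lists per setting over the 21896 genes of the WT1 comparison. Fisher's test called 6% of random 20-gene lists and 33% of 20-gene lists of long genes without enrichment, and the test within length groups 5.5% and 3.5%. With the odds raised 8 times, the shares called were 95.5% and 98.5%. In 10 simulated runs of the overlap test with no planted sharing, 0.421% of peaks overlapped on average and no run passed 0.05, and with 50% planted, 50.1% was recovered on average and 10 of 10 runs passed. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the figures. The depth of the libraries is unknown, so precision is given only as binomial intervals of peak and gene counts. The lists used here hold no values for the input libraries, which entered only as far as the authors used them. The series text names histone marks, but the lists hold no histone values, and histone states were not analysed here. Sequence motifs were not analysed here because no genome sequence was at hand.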

Results

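Chromatin immunoprecipitation followed by sequencing was used to map where 2 transcription factors, WT1 and MAFB, sit on DNA in mouse podocytes, the epithelial cells that form the filtration slits of the kidney glomerulus. WT1 is a zinc finger protein and MAFB a basic leucine zipper protein of the large Maf group, and both are required for podocyte differentiation. The series held 6 libraries in 3 groups, with 2 libraries each for anti-WT1, anti-MAFB and input chromatin that was not immunoprecipitated. The chromatin came from glomeruli captured on magnetic beads, and the labels name the material as isolated podocytes. For each factor the authors deposited 1 list of peaks combined over its libraries, scored by irreproducible discovery rate (IDR), a measure of how well peaks rank alike in replicates. The lists used here hold no read counts or values per library, so the depth is unknown and no replicate error can be given. The p-values below cover chance among peaks or genes and not variation between animals. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

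WT1 occupied far more of the genome than MAFB in these lists. There were 17095 WT1 peaks with a median length of 387.0 bp, covering 8121.1 kb, and 476 MAFB peaks with a median length of 211.5 bp, covering 111.0 kb. WT1 peaks were assigned to 7236 protein-coding genes, 33% of the 21896 in the background, and MAFB peaks to 307, or 1.4%. The IDR score reached its limit of 1000 in 34.9% of WT1 peaks, whereas the highest MAFB score was 805. At the bottom of the lists, 21.2% of WT1 peaks shared the lowest score of 182 and 28.6% of MAFB peaks the lowest score of 114. Antibody and peak number differ between the lists and the depth is unknown, so no test compared scores between the lists.

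The first question was which genomic regions each factor occupied. Promoters, defined by the authors' annotation as within 3 kb of a transcript start, held 8514 WT1 peaks (49.8%, interval 49.1 to 50.6%) and 262 MAFB peaks (55%, interval 50.4 to 59.6%). A transcript start lay inside 33.5% of WT1 peaks and 34.7% of MAFB peaks. Introns held 26.8% of WT1 peaks and 21% of MAFB peaks, and distal intergenic DNA 20.1% and 22.7%. Exons outside promoters held 1.56% of WT1 peaks. About as many peaks lay over 10 kb from the assigned start in both lists, 35.3% for WT1 and 34% for MAFB. The promoter share was higher for MAFB (odds ratio 1.23, two-sided Fisher's exact test, p = 0.0257). This difference was not detectable once 60 MAFB peaks in a dense group on chromosome 9, on chromosome Y and on the mitochondrial genome were left out (218 of 416 peaks, 52.4%, odds ratio 1.11, Fisher's exact p = 0.298). It also did not pass the threshold with promoters drawn at 5 kb (odds ratio 1.14, Fisher's exact p = 0.175) or in the higher-scoring 50% of each list (odds ratio 1.23, p = 0.13).

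WT1 peaks were found at most genes of the podocyte lists. Of the 121 genes in the 5 podocyte lists, 112 had at least 1 WT1 peak. The background held all protein-coding genes and was not limited to genes active in glomeruli. In the slit diaphragm list, the junction between neighbouring foot processes, 20 of 21 genes had one (95.2%, 2.88 times the background share, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 8.2e-09). Trpc6, a cation channel, was the member without a peak. All 21 genes of the basement membrane and adhesion list had a WT1 peak (3.03 times the background share, Fisher's exact test, adjusted p = 5.2e-10). The podocyte transcription factor list had 15 of 16 (93.8%, Fisher's adjusted p = 1.1e-06), with Foxc2 the member without. The cytoskeleton list had 27 of 30 (90%, Fisher's adjusted p = 5.2e-10), without Anln, Avil and Ilk, although a WT1 peak assigned to Rrp8 covers a MAFB peak at the start of Ilk. The list of other podocyte genes had 29 of 33 (87.9%, Fisher's adjusted p = 5.2e-10), without Angpt1, Pla2r1, Ptgds and Sema3a. All of these calls held when genes were compared with an exact test within length deciles, with adjusted p between 3.6e-07 and 1.9e-06. Members without a peak are those with none assigned to them. With gene bodies within 50 kb of a peak midpoint, the transcription factor list had 16 of 16 and the cytoskeleton list 29 of 30. The slit diaphragm list stayed at 20 of 21, and 61.4% of the background was counted.

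**Figure D1:**
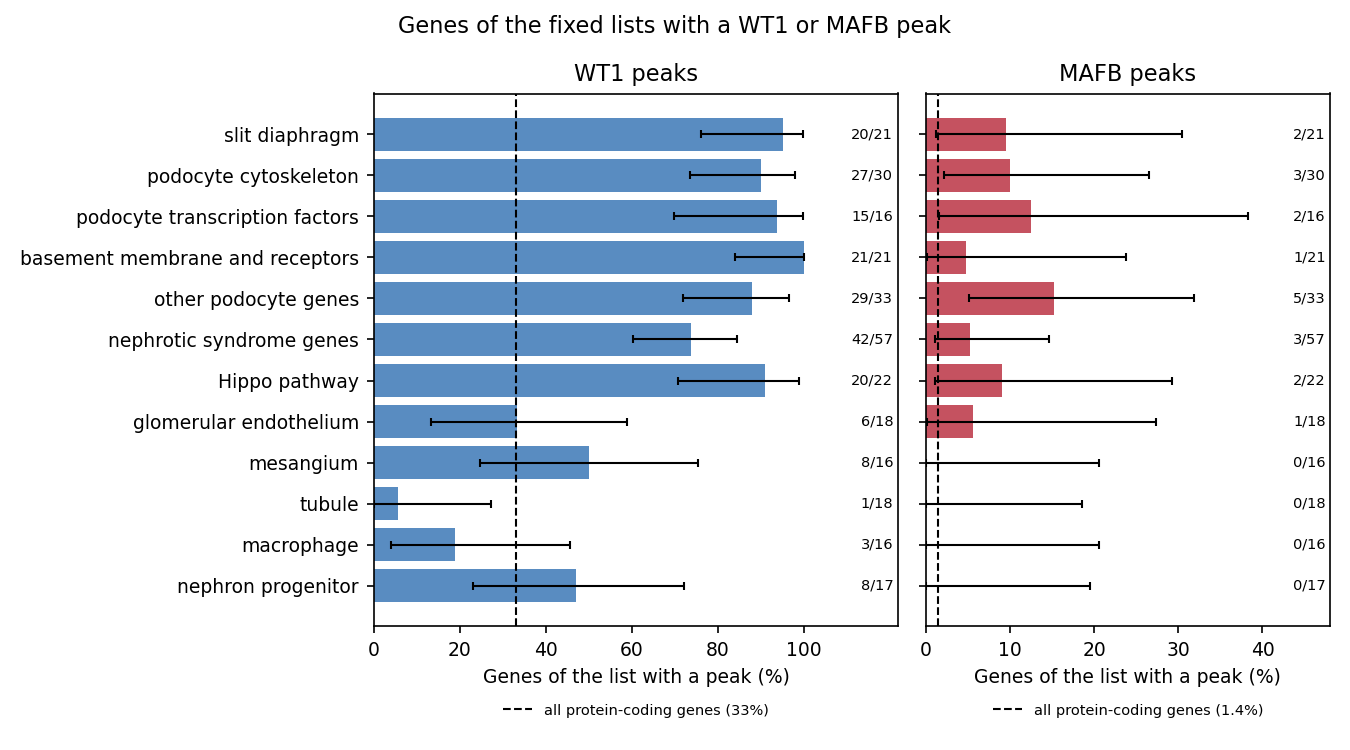
Share of the genes of each fixed list with at least 1 peak of WT1 (left panel, blue) or MAFB (right panel, red), in percent, with exact Clopper-Pearson 95% intervals as bars and the number of genes with a peak over the list size at the right. Dashed lines mark the share of all protein-coding genes, 33% for WT1 and 1.4% for MAFB; the 5 podocyte lists lie between 87.9% and 100% for WT1 and the tubule list at 5.56%.

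Genes of inherited nephrotic syndrome also carried WT1 peaks more often than the background, with 42 of 57 (73.7%, 2.23 times, Fisher's adjusted p = 1.5e-09). This list shares 32 genes with the podocyte lists. Among its other 25 genes, 13 had a WT1 peak (52%, interval 31.3 to 72.2%, Fisher's exact p = 0.0546, and p = 0.298 within length deciles). The coenzyme Q enzymes Coq2, Coq6 and Coq8b and the tRNA-modifying KEOPS complex members Lage3, Osgep, Tprkb and Trp53rkb were among the 15 without an assigned peak. With gene bodies within 50 kb of a peak midpoint, 51 of the 57 genes were counted, against 61.4% of the background. For the Hippo pathway, which controls the coactivators Yap1 and Wwtr1, the count was 20 of 22 (90.9%, Fisher's adjusted p = 5.2e-08), with Lats1 and Tead2 the members without. Outside the 4 genes it shares with the podocyte lists, 16 of 18 Hippo genes had a peak (88.9%, exact test within length deciles, p = 6.5e-05).

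Among protein-coding genes, no list of markers of other cell types in or near the glomerulus had more WT1 peaks than the background at the threshold. WT1 peaks were found at 6 of 18 glomerular endothelial genes (33.3%, Fisher's adjusted p = 1), among them Flt1, Pecam1 and Cdh5. Mesangial genes had 8 of 16 (50%, Fisher's adjusted p = 0.244), including Pdgfrb and Gata3, and nephron progenitor genes 8 of 17 (47.1%, adjusted p = 0.328). Against all annotated genes both of these lists did pass, at 2.95 and 2.77 times the background share (Fisher's adjusted p = 0.00363 and 0.00519). Macrophage genes had 3 of 16 (18.8%, Fisher's adjusted p = 0.328), namely Csf1r, Mpeg1 and Mrc1. Of the 18 tubule genes only Cubn, which encodes the endocytic receptor cubilin, had a WT1 peak (5.56%, 0.168 times the background share, Fisher's adjusted p = 0.0162). The lower share at tubule genes did not pass the threshold under any of 5 other choices of peaks, gene assignment or background, where Fisher's adjusted p lay between 0.051 and 0.453. The share was still 0.196 to 0.327 times the background in 4 of the 5, and 0.814 times with gene bodies within 50 kb. The call held within length deciles (exact test, adjusted p = 0.00684).

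Many podocyte genes carried WT1 peaks in groups. At least 5 peaks were assigned to 13 of 30 cytoskeleton genes (43.3%), 9 of 21 slit diaphragm genes (42.9%) and 12 of 33 other podocyte genes (36.4%), against 2.07% of the background. The shares were lower in the basement membrane list, with 5 of 21 (23.8%, exact test, adjusted p = 0.0106), and in the transcription factor list, with 3 of 16 (18.8%, adjusted p = 0.0234). The nephrotic syndrome list, with 15 of 57 (26.3%, exact test, adjusted p = 2e-08), and the Hippo list, with 4 of 22 (18.2%, adjusted p = 0.023), also passed. For the first 3 lists, 1.19, 1.24 and 1.58 genes were expected by chance within length deciles (exact tests, adjusted p = 3.4e-11, 1.6e-06 and 2e-08). The deciles match gene length only, not the width of intergenic flanks, which also draws peaks by distance. No endothelial, tubule or macrophage gene reached 5 peaks, but 2 of 16 mesangial genes did (Pdgfrb with 6 and Des with 5, exact test, adjusted p = 0.0838), as did 1 of 17 nephron progenitor genes (Bmp7 with 6, adjusted p = 0.456). Synpo, which encodes the actin-binding protein synaptopodin, had 11 WT1 peaks across chr18:60596141-60652330, and Actn4, which encodes an actin crosslinker mutated in familial glomerulosclerosis, had 13.

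In the slit diaphragm list 19 of 21 genes had a WT1 peak at the score limit of 1000, and the 10 named here are those with the longest of these tied peaks, most of which lay over transcript starts. They were Nck2, Fyn, Pard3, Kirrel2, Tjp1, Cldn5, Cd2ap, Kirrel, Magi2 and Prkci. Fyn, a Src family kinase that phosphorylates nephrin, had 12 WT1 peaks, the highest-ranked at chr10:39369601-39370988 over a transcript start. Tjp1, which encodes the junction protein ZO-1, had 10, with the highest-ranked at chr7:65370390-65371480. Cd2ap, an adaptor that links nephrin to actin, had 6, with the highest-ranked at chr17:42876082-42877126. The highest-ranked Kirrel peak instead lay in intron 1 of 15, at chr3:87165160-87166022, and that of Cldn5 was annotated to a 3' UTR, at chr16:18781247-18782304. None of these 10 genes had a MAFB peak assigned to it. The MAFB peak assigned to Nphs1, at chr7:30459562-30459728, nevertheless lies within 3 kb upstream of the Kirrel2 start at 30457652. With gene bodies within 50 kb of a MAFB peak midpoint, 4 of 21 slit diaphragm genes were counted.

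Podocyte transcription factor genes were occupied by WT1, including the genes of both factors under study. Wt1 itself had 4 WT1 peaks, the highest-scoring at chr2:105126171-105127048 over a transcript start with a score of 1000, while the other 3 had the lowest score of 182. Mafb had a promoter peak at chr2:160366377-160367575 with a score of 1000. A further 3 WT1 peaks assigned to Mafb lay in intergenic DNA 46069, 66159 and 84225 bp upstream, with scores of 863, 966 and 866. No MAFB peak was assigned to Wt1 or Mafb. Nr3c1, the glucocorticoid receptor gene, had a single WT1 peak of 2540 bp at chr18:39489193-39491732. Lmx1b, mutated in nail-patella syndrome, had 11 WT1 peaks. The named list was completed by Wwtr1, Tead1, Foxc1, Foxd1, Klf6 and Klf15, each with its highest-ranked WT1 peak at 1000, and the Tead1 peak at chr7:112678901-112680254 also overlapped a MAFB peak.

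In the basement membrane and adhesion list, Itgb5, an integrin subunit, had 12 WT1 peaks and Itga3, the laminin receptor subunit of podocytes, had 7. The highest-ranked Itga3 peak lay over a transcript start at chr11:95076462-95077325. Lama5, the laminin chain of the mature glomerular basement membrane, had 4 WT1 peaks, with the highest-ranked 1298 bp upstream of a start at chr2:180227157-180227987. Col4a5, mutated in Alport syndrome, had a single peak at chrX:141475112-141476133 in its promoter. Itgav, Nid1, Agrn, Itgb1, Sulf1 and Cd151 also had highest-ranked peaks at 1000 in promoters. Over all genes, 5973 WT1 peaks tied at this score, and the longest of them belonged to Foxp1 (3275 bp), Fgfr2 (2683 bp), Midn (2635 bp), Nr3c1, Sema4c, Ptch1, Dnmt3a, Ncoa2, Ppp3ca and Zfp827. All 10 were promoter peaks without an overlapping MAFB peak.

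MAFB peaks were found at few members of the same lists. Only the list of other podocyte genes passed the test, with 5 of 33 genes (15.2%, interval 5.11 to 31.9%, 10.8 times the background share of 1.4%, Fisher's adjusted p = 0.00108, and 0.00432 within length deciles). These were Vegfa, the growth factor that maintains glomerular endothelium, Efnb1, an ephrin of the slit diaphragm, Srgap1, Clic3 and Enpep. With peaks limited to 5 kb from a start, this call was lost (Fisher's adjusted p = 0.521). The slit diaphragm list had 2 of 21 genes (Fisher's adjusted p = 0.0903), Nphs1 and Nphs2, and the transcription factor list 2 of 16 (adjusted p = 0.0826), Tcf21 and Lmx1b. These counts follow the assignment of peaks to genes. Tead1, in the transcription factor and Hippo lists, is not counted, because the MAFB peak on its WT1 promoter peak was assigned elsewhere. The cytoskeleton list had 3 of 30 (Fisher's adjusted p = 0.0502), Palld, Ilk and Cgnl1. The basement membrane list had 1 of 21 (Itgb5, Fisher's adjusted p = 0.385), the nephrotic syndrome list 3 of 57 (adjusted p = 0.0917) and the Hippo list 2 of 22 (Amotl1 and Vgll4, adjusted p = 0.0903). The shares of these lists that did not pass were 3.4 to 8.92 times the background, with 0.25 to 1.11 genes expected per list within length deciles. At such low expected counts, a missed threshold does not show a lack of enrichment. Over the 5 podocyte lists, 13 of 121 genes had a MAFB peak, and no test was run on this total. In the endothelium list 1 of 18 genes, Flt1, had a MAFB peak (3.96 times the background share), and no mesangial, tubule, macrophage or nephron progenitor gene did. The MAFB peaks of Enpep, Cgnl1, Amotl1 and Flt1 had the lowest score of 114. In the higher-scoring 50% of the MAFB list, 4 lists passed the threshold.

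The central comparison was how often both factors occupied the same place. A WT1 peak overlapped 255 of the 476 MAFB peaks (53.6%, interval 49 to 58.1%), and 255 of the 17095 WT1 peaks were involved (1.49%). After random placement of the MAFB peaks along their chromosomes, 2.32 peaks (0.488%) overlapped on average and 11 at most in 100000 placements (one-sided permutation test, p = 1e-05, the smallest these placements can give). Placement at the same distance to other transcript starts in the lists gave 117.7 peaks on average (24.7%) and 152 at most (permutation p = 1e-05, again the smallest possible). The share was 61.3% without the same 60 MAFB peaks on chromosomes 9 and Y and the mitochondrial genome, and 38.7% in the higher-scoring 50% of each list, where fewer WT1 peaks can be met.

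**Figure D2:**
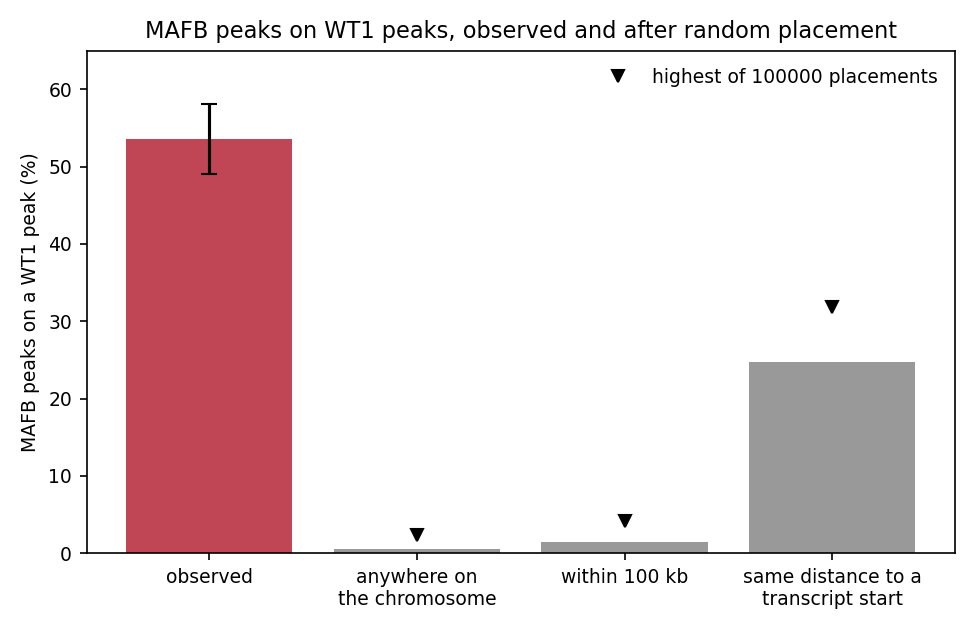
Percent of the 476 MAFB peaks that overlap a WT1 peak, as observed (red, with the exact 95% interval) and as the mean of 100000 random placements of 3 kinds (grey). Triangles mark the highest placement of each kind, 2.31%, 4.2% and 31.9%, all below the observed 53.6%.

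At podocyte genes the MAFB peaks nearly always lay on a WT1 peak. By assignment, the 5 podocyte lists held 14 MAFB peaks at 13 genes. Of these 14 peaks, 13 overlapped a WT1 peak (92.9%, interval 66.1 to 99.8%), against 242 of the 462 other MAFB peaks (52.4%, odds ratio 11.8, two-sided Fisher's exact test, p = 0.00218). The MAFB peak on the WT1 promoter peak of Tead1 is among the other peaks. Without the 60 peaks on chromosomes 9 and Y and the mitochondrial genome the comparison was with 242 of 402 (60.2%, odds ratio 8.6, Fisher's exact p = 0.0119). An intronic peak in Palld was the exception. Of the 14, 3 lay in promoters. At Nphs1, which encodes nephrin, the MAFB peak at chr7:30459562-30459728 (score 555) reached the transcript start at 30459725 and lay inside a WT1 peak at chr7:30459356-30459800 with a score of 1000. At Nphs2, which encodes podocin, the MAFB peak at chr1:156309320-156309613 (score 591) lay 1114 bp upstream of the start, inside a WT1 peak at chr1:156309146-156309691 with a score of 1000. A second WT1 peak covered the Nphs2 start with a score of 369. Ilk had the remaining promoter peak, at chr7:105736410-105736735.

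The other 11 MAFB peaks of these genes lay in introns or intergenic DNA, except the peak at Clic3, which was classed as downstream of a gene. In Lmx1b the MAFB peak at chr2:33606012-33606128 (score 570) fell in intron 2 of 7, within a WT1 peak of 1235 bp. Tcf21, a basic helix-loop-helix factor of developing podocytes, had a MAFB peak 48276 bp upstream, at chr10:22868404-22868624 (score 588), inside a WT1 peak with a score of 1000. At Itgb5 a MAFB peak in intron 3 of 14, at chr16:33872135-33872340 (score 593), lay inside a WT1 peak with a score of 1000. Vegfa had MAFB peaks at chr17:46052202-46052365 (score 577) and at chr17:45931244-45931494 (score 114), 19825 bp upstream and 89878 bp downstream of the assigned starts, both on WT1 peaks. Podxl, which encodes the surface sialoprotein podocalyxin, had 3 WT1 peaks, with its promoter peak at chr6:31563484-31564167, and no MAFB peak.

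**Figure D3:**
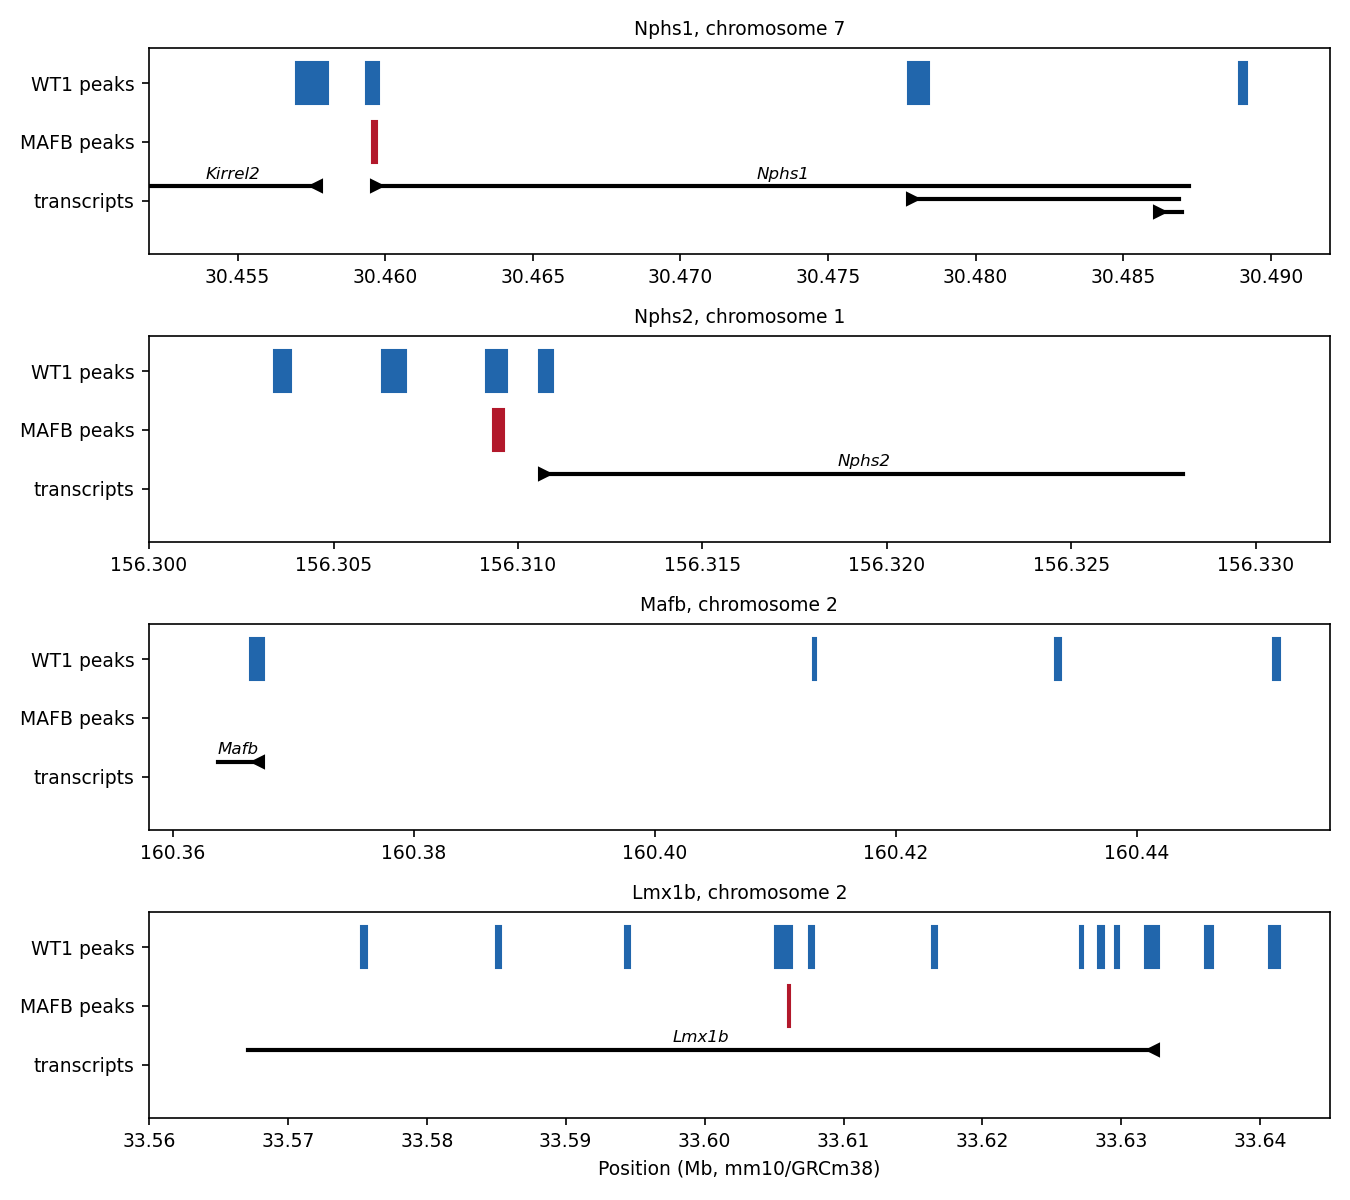
WT1 peaks (blue) and MAFB peaks (red) around Nphs1, Nphs2, Mafb and Lmx1b, with the transcripts the authors assigned (black, arrowheads at the start), against position in Mb on mm10/GRCm38; bars are drawn to scale. A MAFB peak lies on a WT1 peak at Nphs1, Nphs2 and Lmx1b, and none is present at Mafb.

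Among all shared regions ranked by MAFB score, podocyte genes did not lead. The 15 named were Gm8882, D17Wsu104e, Gm23186, Zfp768, Gm6216, Tbpl1, Rbm25, Sh3pxd2b, Mettl18, Zfp41, Rps27l, Pfdn5, Igkv8-30, Hibch and Gm27760. The highest, at chr6:132463692-132463814 (score 805), was intergenic and 99558 bp from the start of Gm8882. Sh3pxd2b, which encodes a podosome scaffold, had a shared peak in intron 3 of 12 at chr11:32383790-32384143 with a MAFB score of 662 and a WT1 score of 1000. The shared promoter peaks of Rbm25, a splicing factor gene, and Pfdn5, a prefoldin subunit gene, had MAFB scores of 681 and 653 but the lowest WT1 score of 182. Of the 10 highest-scoring MAFB peaks, 4 overlapped a WT1 peak, those at Gm8882, D17Wsu104e, Gm23186 and Zfp768, and 1 was in a promoter. The other 6 were assigned to RP23-231B19.3, Myo7a, Olfr854, Gm24947, Gm26535 and Gm26928.

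MAFB peaks outside promoters lay on WT1 peaks more often than those in promoters. The counts were 134 of 214 (62.6%, interval 55.8 to 69.1%) and 121 of 262 (46.2%, interval 40 to 52.4%), with an odds ratio of 0.512 for promoters (two-sided Fisher's exact test, p = 0.00044). The promoter count includes 43 peaks of the chromosome 9 group, none of them on a WT1 peak. Without the 60 peaks on chromosomes 9 and Y and the mitochondrial genome, the counts were 134 of 198 (67.7%) and 121 of 218 (55.5%). The odds ratio was then 0.596 (Fisher's exact p = 0.0119). The difference did not pass the threshold among the 340 MAFB peaks above the lowest score (odds ratio 0.732, Fisher's exact p = 0.183). This comparison was added after the data were examined.

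WT1 peaks that carried a MAFB peak ranked higher than other WT1 peaks. Their median score was 1000 (interquartile range 436.0 to 1000) against 624.0 (328.0 to 1000), a difference of 376.0, which is a lower limit because the first median sits at the score limit (two-sided permutation test, 100000 resamples, p = 1e-05, the smallest they can give). The score limit was reached by 143 of 255 (56.1%) against 5830 of 16840 (34.6%, odds ratio 2.41, Fisher's exact test, p = 4.4e-12). Outside promoters the medians were 1000 and 604.0 (permutation p = 1e-05), whereas in promoters they were 752.0 and 645.0, a difference of 107.0 that did not pass the threshold (p = 0.244). The promoter share itself was 47.5% with a MAFB peak and 49.8% without (Fisher's exact p = 0.488).

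Counted by gene, most MAFB-assigned genes also had a WT1 peak somewhere. Of the 307 protein-coding genes with a MAFB peak, 221 had one (72%, interval 66.6 to 76.9%) against 33% of the background, where 101.5 genes would be expected (odds ratio 5.34, two-sided Fisher's exact test, p = 1e-44). Within length deciles 122.8 were expected, and the observed number was 1.8 times that (exact p = 1.5e-32). Overlapping peaks enter this count, so it is not independent of the peak overlap, and no count was made without them.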

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

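Settings without the 60 MAFB peaks of the chromosome 9 group, chromosome Y and the mitochondrial genome, with the score of 540, with WT1 peaks below the highest score, with gene bodies within 50 kb of a peak, with peak length in place of the score, the gene-level overlap within length deciles and all alternatives to the promoter comparison of shared MAFB peaks were chosen after the data were examined. The overlap of the lists stayed above random placement (permutation p = 1e-05, the smallest possible) in all 8 alternatives, at 23.5% to 61.3% of MAFB peaks, though stricter lists share fewer peaks: 92 in the higher-scoring 50% of each list and 101 at a score of 540, against 255. The gene-level overlap kept an odds ratio of 3.65 to 12.7, and was 1.8 times the expected number within length deciles. The same number of lists, 7, was enriched among WT1 genes in all alternatives except the background of all annotated genes, where it was 9 with the mesangium and nephron progenitor lists. The higher MAFB promoter share lost its call with promoters within 5 kb (odds ratio 1.14), in the higher-scoring 50% (1.23), without those 60 peaks (1.11) and at a score of 540 (1.26). The lower sharing of promoter MAFB peaks kept its call without those 60 peaks (odds ratio 0.596, against 0.512 for all peaks). It lost its call above the lowest score (odds ratio 0.732) and at a score of 540 (0.676), with fewer peaks in each. Both limits also remove the chromosome 9 group, where 43 of 45 MAFB peaks were promoter peaks and none lay on a WT1 peak. The score difference of WT1 peaks lost its call in promoters (107.0). The count of lists enriched among MAFB genes was 1, and became 0 within 5 kb of a start, 4 in the higher-scoring 50%, 6 against all annotated genes and 4 at a score of 540. Fewer peaks entered several of these settings, and the cause of the changes was not tested. No difference past the threshold reversed. For single lists, 90 values kept their direction and side of the threshold, 13 newly passed it and 6 no longer did, 5 of them the tubule list. A further 11 values, none past the threshold in either setting, changed direction against the background share, and the cause was not tested. For WT1 these were the endothelium list, at 1.01 times and then 0.978 (within 5 kb), 0.845 (higher-scoring 50%) and 0.788 (score of 540), the nephron progenitor list, at 1.42 and then 0.829 (within 5 kb) and 0.958 (gene bodies within 50 kb), and the macrophage list, at 0.567 and then 1.1 (all annotated genes). For MAFB no gene was left in the transcription factor and basement membrane lists within 5 kb, or in the endothelium list in the higher-scoring 50% and at a score of 540, so these went to 0 times, and the macrophage list went from 0 to 1.35 with gene bodies within 50 kb. No paired analysis was possible because the lists hold no value per library, and leaving out a replicate was not possible for the same reason. Histone classes, motifs and genes with a start within 50 kb were planned and not run, since the lists have no histone values and the reference has neither sequence nor strand. Unknown depth limits the reading of the small MAFB list: a region without a MAFB peak is not shown to lack MAFB.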

Other observations

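The family counts, the peak-length comparison and the chromosome 9 test below were chosen only after the results were seen; the other explanations were set out after the lists were first read but before their tests were run. Beyond the fixed lists, 20 gene families defined by their symbols were counted, with exact tests within length deciles adjusted over the families. Homeobox cluster genes had WT1 peaks at 20 of 39 members (51.3%, 9.11 expected, exact test, adjusted p = 0.00053), forkhead factors at 21 of 44 (47.7%, 12.8 expected, adjusted p = 0.0186) and Krueppel-like factors at 11 of 17 (64.7%, 5.73 expected, adjusted p = 0.0186). With Fisher's exact test, used for the lists of the report, the homeobox and forkhead calls did not pass (adjusted p = 0.0559 and 0.105). Rho guanine nucleotide exchange factors (16 of 25, Fisher's adjusted p = 0.00688) and semaphorins (12 of 20, 0.0389) passed with that test but not within length deciles (0.189 and 0.28). Rho GTPase-activating proteins, which switch off the GTPases that shape the actin cytoskeleton, had 25 of 34 (73.5%, 16.6 expected, adjusted p = 0.0145). Families with fewer WT1 peaks than expected were cytochrome P450 enzymes (12 of 99, 34.3 expected, exact test, adjusted p = 1.7e-06), the Slc22 organic ion transporters of the tubule and liver (4 of 25, 10.3 expected, adjusted p = 0.0236, but 0.146 with Fisher's test), keratins (2 of 53, adjusted p = 0.00022), olfactory receptors (3 of 1110, adjusted p = 4.1e-28) and vomeronasal receptors (1 of 353, adjusted p = 1.7e-27). Ribosomal protein genes had 19 of 80 with a WT1 peak (exact test, adjusted p = 0.379). For MAFB no family passed the threshold within length deciles, and olfactory receptors, with 1 of 1110, passed with Fisher's test (adjusted p = 8.9e-05, and 0.742 within length deciles).

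The genes with the most WT1 peaks were Tns3, which encodes a focal adhesion protein, with 23, and Smad6, which encodes an inhibitor of BMP signalling, with 21. Gse1 and Zbtb7c followed with 20 each, Apbb2 and Maml3 with 19, and Ncor2 and Zfp423 with 18. Further down were the RhoGAP gene Dlc1 with 14, and Smad3, Kank1, Parva and Vegfa with 12 each. Most of these genes are long, with Gse1 at 352.9 kb and Tns3 at 233.1 kb, but Vegfa spans 15.4 kb and Efnb1, with 11 peaks, 13 kb. Promoter peaks made up 3 of the 12 at Vegfa and 0 of the 11 at Efnb1. Assignment by distance also counts peaks in wide intergenic flanks.

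The first pattern weighed is that MAFB peaks lie on WT1 peaks far above chance. A shared preference for promoters does not explain all of it, since no placement at matched distances to transcript starts exceeded 31.9%, against 53.6% observed. These placements still gave 24.7% on average. They used only transcripts of the 2 lists, which already have an assigned peak, so 24.7% is not the level for promoters in general. Promoter and other MAFB peaks were not placed separately, so how much of the sharing at promoters a promoter preference explains is not decided. The density of WT1 peaks averaged over 100 kb around each MAFB peak does not account for the pattern, since placements within 100 kb reached at most 4.2%. These placements ignored transcript starts, so they do not decide on density close to starts or over shorter distances. Regions of the highest WT1 score alone do not account for the pattern either, as 23.5% of MAFB peaks lay on WT1 peaks below that score. Shared occupancy at podocyte genes is one candidate explanation, with an odds ratio of 11.8 for MAFB peaks at podocyte-list genes, but these are 13 of the 255 shared peaks. Open chromatin that either antibody could enrich, input libraries used for both factors and signal from other glomerular cells stay untested, because no accessibility data, control immunoprecipitation or library values were used here.

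The second pattern is the 221 MAFB peaks away from WT1 peaks. Irreproducible peaks at the bottom of the list do not account for them as a whole, because 40.6% of the 340 MAFB peaks above the lowest score also had no WT1 peak (interval 35.3 to 46%). At the lowest score 53 of 136 peaks lay on a WT1 peak, against 202 of 340 above it (odds ratio 0.436, Fisher's exact p = 6.8e-05). Without the 60 peaks on chromosomes 9 and Y and the mitochondrial genome no difference was detectable. The counts were then 53 of 88 (60.2%) and 202 of 328 (61.6%, odds ratio 0.945, Fisher's exact p = 0.807). Promoters of ribosomal, respiratory chain and proteasome genes were 8 of 141 promoter peaks off WT1 and 2 of 121 on WT1 (odds ratio 3.58, Fisher's exact p = 0.113). The 141 include 43 promoter peaks of the chromosome 9 group, all at numbered Gm gene models, and no test was run without them. These counts therefore do not decide whether MAFB may occupy such promoters without WT1. Length goes with this split: without the 60 peaks of the chromosome 9 group, chromosome Y and the mitochondrial genome, 43 of 105 MAFB peaks of up to 157.0 bp lay on a WT1 peak (41%), against 212 of 311 longer ones (68.2%, odds ratio 0.324, Fisher's exact p = 1.5e-06). MAFB acting alone, and WT1 peaks missed at the unknown depth, stay open.

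The third pattern is a dense group of 45 MAFB peaks in 35.3 kb at chr9:3001665-3036952, all at the lowest MAFB score and none on a WT1 peak. All of them, 100%, were assigned to numbered Gm gene models, 10 in number, and 43 were classed as promoter peaks. Reads of repeated sequence next to the centromere are a candidate explanation that goes with this assignment, which was tested only after the group was seen; no sequence was used to test it directly. The WT1 list had no peak in this span, and its first peak on the chromosome starts at 4309117. No biological explanation was tested.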
